A study of Mus musculus with 10 samples.

How the data were processed

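The data are RNA sequencing counts of 10 jejunum libraries, 5 without the villin-Cre-ERT2 transgene (control) and 5 with it (RetSat ko), grouped by the genotype in the labels. The labels list them as separate samples of a mouse study without stating outright that each came from a different animal, so p-values measure the spread between these samples. Per the labels' protocols, RNA was isolated with RNeasy columns, treated with DNase and made into libraries with the NEBNext Ultra II RNA kit.

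The deposited values are raw counts of reads per gene, 1 library per file. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR to GRCm39 (mm39). Per the file headers, the counts were made with featureCounts 2.0.1 over exons grouped by gene in the GENCODE mouse release M28 annotation, each read going to the gene with the largest overlap. The command in the headers has no option for strand, for read pairs or for reads with several alignments. Counting without strand means that overlapping genes on opposite strands cannot be separated. If reads came in pairs, which is not given in the sources used here, each fragment can count more than 1 time, so counting intervals are lower limits of the error. Reads that fit several near-identical genes are not counted by default, which makes members of such families and pseudogenes uncertain.

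The files hold 55414 gene identifiers. Symbols were matched by identifier for 52081 of them (94.0%), and 0.81% of all counts lie on identifiers without a symbol. Gene types and transcript sequences came from GENCODE M21, which belongs to an older build, so every coordinate is the one in the files (GRCm39). Transcript similarity was searched with blastn 2.17.0.

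Counts were analysed in R 4.3.3. Genes were kept with filterByExpr and normalized with TMM factors, and the genotypes were compared with edgeR 4.0.16 (quasi-likelihood F-test, robust estimates, no covariates), with Benjamini-Hochberg adjustment over 18654 genes and a threshold of 0.05. CPM values are counts per 1000000 of the TMM-adjusted library size. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided, adjusted over 36 lists, and again with an estimated correlation and with fry. For each list the number of members past 0.05 was counted over all genes and adjusted over the list alone. Principal components used log2 CPM with a prior count of 2 over the 500 most variable genes. Single values per library were compared with two-sided exact permutation tests of 5 against 5 samples, where the smallest possible p is 0.00794. The clustering of called genes was tested per chromosome with Fisher's exact test, without Retsat.

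The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Retsat, then called genes of at least 1 CPM without a predicted-type symbol (the 10 with the largest rise and the 10 with the largest fall), filled to 20 with the smallest unadjusted p. It adds the 4 members with the smallest p of each called list, 6 of the retinoid list, and up to 2 of other lists described. Some members that the rule takes are not reported here. Genes named outside it are said to be so. Of the 20 genes by rank, 6 were past the threshold.

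Depth was 102844680 to 128730695 counts per library. Where a group had no counts, the limit is the 3 counts that a count of 0 allows over the group, and intervals are exact 95% Poisson intervals. Both cover counting error only. No pair of libraries was a duplicate, since over the 45 pairs the chi-square per degree of freedom of their counts was at least 56.3.

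The steps were tested on simulated counts with the means, dispersions and library sizes of these samples (18218 genes tested, with 50 changed at each size). For RetSat ko against control, 40% of genes changed 1.5-fold, 90% of those changed 2-fold and 98% of those changed 4-fold and 8-fold were recovered, with 6 false calls among 174. A list shifted 1.3-fold was recovered and 0 other lists were called. Genes were drawn independently of each other there, so false calls of lists whose genes vary together could not appear. The genes changed by these folds were taken only from those above 1 CPM in control, so recovery at lower levels was not tested.

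Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, non-robust estimates, the replicate number as a block, 1 surrogate variable from sva 3.50.0, leaving out each library in turn, larger numbers of genes in the principal components, and a threshold of 0.1 in the chromosome test. Fits without the libraries richest in acinar or B cell transcripts, with the acinar score as covariate, list tests without RetSat ko 1 under estimated correlation and fry, a chromosome test without Gm45053 and a ribosomal protein list were added after seeing the data.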

Results

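Gene expression was measured by RNA sequencing of jejunum, the middle part of the small intestine, from 10 male C57BL/6J samples carrying floxed alleles of Retsat, the gene of retinol saturase, an enzyme that acts on retinol (vitamin A). In 5 samples the villin-Cre-ERT2 transgene was absent (control) and in 5 it was present (RetSat ko). This transgene drives, in the intestinal epithelium, a Cre recombinase fused to a modified hormone-binding domain of the oestrogen receptor, which becomes active with tamoxifen. Mice of both genotypes received tamoxifen for 5 days and then a diet with 60% of its energy from fat for 14 weeks. The comparison asks how the jejunal transcriptome under this diet differs between these genotypes. Loss of the enzyme and presence of the active Cre recombinase go together in this design, so their effects cannot be told apart. Total counts per library lay between 102844680 and 128730695, and 24559 to 26180 genes had at least 1 count. In units of 1000000 counts, the total was 117.7 ± 6.26 in control and 116.0 ± 10.4 in RetSat ko (SD, n = 5 each). Mitochondrial transcripts took 1.59 ± 0.254% of the counts in control and 1.80 ± 0.327% in RetSat ko, and the 10 most abundant genes took 8.78 ± 0.895% and 8.38 ± 0.773%. The number of genes detected was 25117 ± 576 in control and 25546 ± 622 in RetSat ko. None of these 4 measures was found to differ between the genotypes (two-sided exact permutation tests, adjusted p from 0.571 to 0.746).

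Retsat itself (ENSMUSG00000056666.14, chromosome 6, 72575458 to 72585408, plus strand, GRCm39) was lower in every RetSat ko library than in every control library. Its level was 440.6 ± 101 CPM (counts per 1000000 counts of the library) in control and 19.6 ± 7.76 CPM in RetSat ko (SD, n = 5 each), so that 4.45% of the control mean remained. The control libraries held 340 to 576 CPM. RetSat ko 1 to 4 held 15.4 to 16.8 CPM and RetSat ko 5 held 33.4 CPM. The log2 fold change was -4.49 ± 0.277 (SE) with an adjusted p of 0.000101 in edgeR's quasi-likelihood test. The two-sided exact permutation test of the CPM values gave p = 0.00794, the smallest p that 5 against 5 samples allow. Raw counts of Retsat were 39413 to 61634 per control library and 1715 to 4636 per RetSat ko library.

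Between the genotypes, 6 of 18654 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4 of them higher and 2 lower in RetSat ko. Esr1, the protein-coding gene of oestrogen receptor alpha (ENSMUSG00000019768.17, chromosome 10, 4561593 to 4955614), rose from 0.596 ± 0.0742 to 38.3 ± 4.73 CPM (SD, n = 5 each), a log2 fold change of 6.00 ± 0.126 (SE) with an edgeR adjusted p of 6.08e-11. The Cre-ERT2 transgene, present only in the RetSat ko samples, carries a modified hormone-binding domain of this receptor. Its reads may have been counted for Esr1, which gene counts cannot tell apart from a response of the gene. The other 3 genes that rose lie on distal chromosome 6 and are annotated as pseudogenes. BC064078 (ENSMUSG00000087150.8, 128969915 to 128985003) rose from 1.08 ± 0.356 to 6.46 ± 1.33 CPM, with an edgeR log2 fold change of 2.58 ± 0.226 and an adjusted p of 0.000395. Gm45063 (ENSMUSG00000108002.2, 132439465 to 132439936) and Gm5154 (ENSMUSG00000108041.2, 132415494 to 132418685) had 0 counts in all 5 control libraries. In the RetSat ko libraries they had 59 to 108 and 17 to 41 counts. Against the 3 counts that a group total of 0 allows, Gm45063 was at least 127-fold higher and Gm5154 at least 40.7-fold higher, with edgeR adjusted p of 0.000395 and 0.0156. Besides Retsat, Gm45053 fell by 1.35 ± 0.165 on the log2 scale (edgeR adjusted p = 0.00945). Gm45053 (ENSMUSG00000108368.2, a locus of unproven type at 72579987 to 72582485) lies inside the Retsat locus on the opposite strand, and the counting command sets no strand, so its reads and those of Retsat cannot be told apart. The call of Gm5154 was lost without RetSat ko 2, without RetSat ko 3 and without RetSat ko 5, with edgeR adjusted p of 0.0551, 0.0906 and 0.0592. Without the 4 libraries highest in acinar transcripts, and without the 3 libraries highest in B cell transcripts, the calls of Gm5154 (edgeR adjusted p = 0.144 and 0.593) and of Gm45053 (0.102 and 0.117) were lost as well. Retsat was not called without the acinar-rich libraries (edgeR adjusted p = 0.0918). These fits held 3 against 3 and 4 against 3 libraries, and the log2 fold change of Gm45053 was -1.35 in each, as with all 10. That of Gm5154 was 7.746 and 7.7, against 7.655 with all 10. That of Retsat was -4.51 without the acinar-rich libraries.

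**Figure D1:**
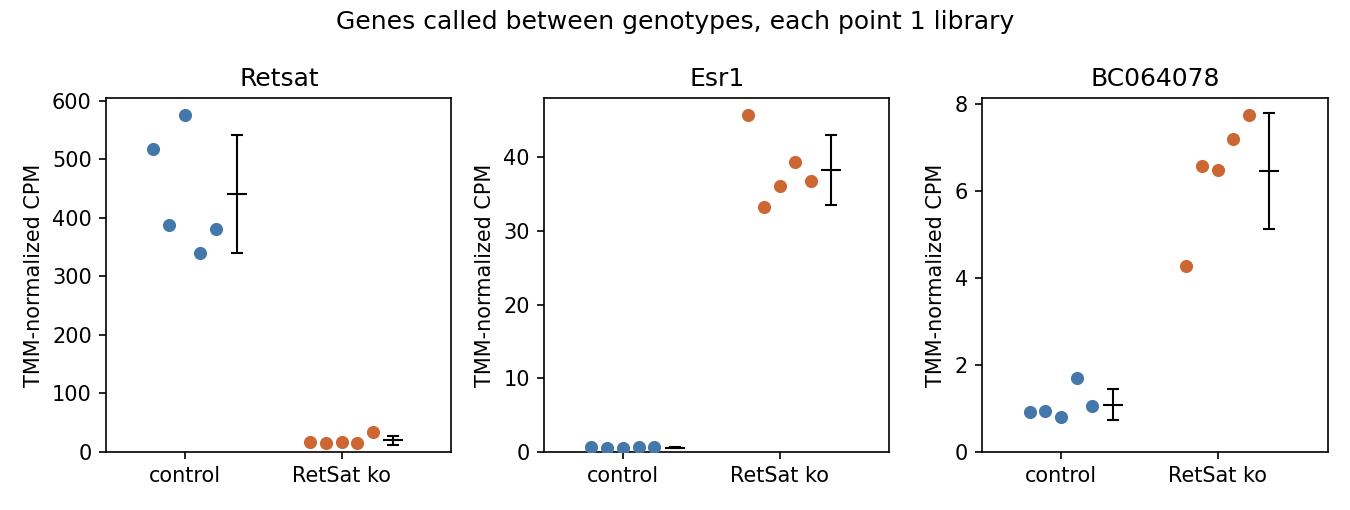
Expression of Retsat, Esr1 and BC064078 in CPM on linear axes, each point being 1 library of control (blue) or RetSat ko (orange), with the mean and SD of the 5 libraries as black bars. Retsat lay at 340 CPM or more in control and at 33.4 CPM or less in RetSat ko, while Esr1 and BC064078 were higher in every RetSat ko library than in every control library. Counts of Esr1 may include reads of the Cre-ERT2 transgene, which only the RetSat ko samples carry.

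The 14 genes with the next smallest p did not pass the threshold in edgeR (adjusted p from 0.0563 to 0.216), although in each of them all 5 RetSat ko libraries lay on 1 side of all 5 control libraries. Higher values in RetSat ko were seen for Pglyrp1, a peptidoglycan recognition protein, with a log2 fold change of 0.43 ± 0.0714, for Safb with 0.38 ± 0.0657, for Dynll1 with 0.48 ± 0.0842 and for Hspe1, a mitochondrial chaperonin, with 0.41 ± 0.0727. D030056L22Rik had 0.46 ± 0.0891, Txnl4a 0.29 ± 0.0572 and Gm44215, at 128668036 to 128670746 on chromosome 6, 3.81 ± 0.572. Lower values were seen for Abcg8, a subunit of the sterol exporter of the brush border, with -0.47 ± 0.0783, for March7 with -0.49 ± 0.0744, for Numa1 with -0.40 ± 0.0678 and for Nedd9 with -0.48 ± 0.0844. Txlng had -0.44 ± 0.0826, Tnfsf10, the death ligand TRAIL, -0.40 ± 0.0760, and Gm45769, at 133087437 to 133089264 on chromosome 6, -0.84 ± 0.161. Over all tested genes, 2283 had an unadjusted p under 0.05, where 932.7 are expected without any difference. That number was 4496 without RetSat ko 1 and 831 without the 3 libraries highest in B cell transcripts. Gm44215 passed the threshold without control 5 and without RetSat ko 4 (edgeR adjusted p = 0.0489 and 0.0144), and Abcg8 passed it without RetSat ko 4 (0.0326). Without a filter on low counts, March7, Gm44215 and Abcg8 passed it (edgeR adjusted p = 0.0278, 0.0390 and 0.0390). With sample weights, limma-voom called March7, Abcg8, Pglyrp1 and Numa1 (adjusted p from 0.0349 to 0.0364). All 14 passed it without RetSat ko 1 (edgeR adjusted p from 0.0216 to 0.0319). DESeq2 called all of them but Gm44215 and Gm45769, to which it gave no adjusted p.

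The number of called genes depended on 1 library, RetSat ko 1. Without it, 846 of 19001 tested genes passed the threshold in edgeR, 371 higher and 475 lower in RetSat ko, and the 6 genes named above as called were among them. In 88.95% of these genes RetSat ko 1 lay nearer to the control mean than to the mean of RetSat ko 2 to 5, which the choice of genes without that library itself favours. With all 10 libraries, DESeq2 called 123 genes, 67 higher and 56 lower. Retsat in RetSat ko 1 was 16.8 CPM, against 15.4 to 16.4 CPM in RetSat ko 2 to 4.

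Genes of lipid handling stood mostly on 1 side. Of 31 tested genes for fat absorption and chylomicron assembly, 30 had a negative log2 fold change in RetSat ko (median -0.20). The 4 with the smallest p were Abcg8 and Abcg5, which export sterols, with -0.47 and -0.36, Apob, the structural protein of chylomicrons, with -0.49, and Mttp, which loads lipid onto it, with -0.40. In edgeR none of the 31 passed over all genes tested, and 2 (Abcg8 and Abcg5) passed when adjusted over the list alone. DESeq2 called these 2 over all genes (adjusted p = 3.86e-05 and 0.0413). Of 27 genes for fatty acid oxidation, ketogenesis and PPAR alpha targets, 26 were negative (median -0.21), among them Ppara with -0.54, Acadm with -0.19 and Acadvl with -0.20. None passed over all genes or adjusted over the list alone. In the camera set test on limma-voom values with a preset correlation, both lists passed (adjusted p = 3.40e-07 and 3.79e-08), and neither did with a correlation estimated from the data (adjusted p = 0.542 and 0.533 with an estimated correlation). Leaving out RetSat ko 1, 4 genes of the fat absorption list were lower over all genes in edgeR (Abcg8, Abcg5, Apob and Tm6sf2), as was 1 gene of the oxidation list (Ehhadh). In that fit 475 of all 19001 tested genes were lower. Tm6sf2 and Ehhadh were chosen after their values were seen. General markers of absorptive enterocytes, the cells that express most of these genes, had a median of -0.35 over their list (adjusted p = 0.533 with an estimated correlation), with no member past the threshold. Without RetSat ko 2 the voom median of the fat absorption list was -0.13, against -0.20 with all libraries.

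Genes of lipid synthesis stood mostly on the other side. Of 24 cholesterol synthesis genes, 20 were positive (median 0.23). Mvd had a log2 fold change of 0.49 ± 0.121, Fdps 0.40 ± 0.105, Mvk 0.37 ± 0.109 and Idi1 0.38 ± 0.120, all enzymes of the mevalonate pathway. In edgeR none passed over all genes tested and 9 were higher when adjusted over the list alone. DESeq2 called 1 over all genes, Mvd (adjusted p = 0.0481). Of 16 genes for fatty acid synthesis and desaturation, 12 were positive (median 0.17), with 1.31 for Thrsp, 0.28 for Elovl5, 0.51 for Scd2 and 0.23 for Fasn. None passed over all genes and 1 (Thrsp) was higher when adjusted over the list alone. Camera with the preset correlation called both lists (adjusted p = 3.68e-05 and 0.0435), and neither with an estimated correlation (adjusted p = 0.634 for each). The cholesterol call was lost without RetSat ko 1 (voom median 0.12 against 0.20 with all, camera adjusted p = 0.103), when 1 member, Sc5d, was lower over all genes. With sample weights in limma-voom it was kept (median 0.11, camera adjusted p = 0.0354). It was also lost without the 4 libraries highest in acinar transcripts, where the median was 0.015 and the test pointed to lower values (camera adjusted p = 0.872). The call for fatty acid synthesis was lost without control 4 (0.207), control 5 (0.0581), RetSat ko 2 (0.0594), RetSat ko 4 (0.0896) or RetSat ko 5 (0.118), while without RetSat ko 1 it was kept (0.0162) and 3 members were higher over all genes (Thrsp, Scd2 and Fads2). It was also lost with upper-quartile factors (0.0597), with the filter of 1 CPM (0.123), without the 4 libraries highest in acinar transcripts (0.127) and without the 3 libraries highest in B cell transcripts (0.1). Its voom median, 0.16 with all libraries, was 0.10 with the filter of 1 CPM, 0.24 without the acinar-rich and 0.14 without the B cell-rich libraries. Adipocyte transcripts were high in the same libraries, since RetSat ko 5 and ko 4 had the highest scores of both the fatty acid synthesis list (0.53 and 0.32) and the adipocyte list (2.48 and 2.01), and Thrsp was at 2.61 and 1.38 CPM there against 0.647 to 1.08 CPM in RetSat ko 1 to 3. Sc5d and Fads2 were chosen after their values were seen.

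Of the 28 tested genes for retinoid metabolism and signalling, the pathway of the deleted enzyme, 11 were positive and 17 negative (median -0.097), and in edgeR none passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. DESeq2 called 1 of them, Adh1 (adjusted p = 0.0351), and limma-voom 0. The list was not called (camera adjusted p = 0.180, and 0.533 with an estimated correlation). The members with the smallest p were the retinol dehydrogenases Adh1 and Adh4, with log2 fold changes of -0.45 ± 0.124 and -0.61 ± 0.176, the retinol carriers Rbp4 and Ttr with 0.60 ± 0.244 and 0.57 ± 0.246, and the nuclear receptors Rxra and Rara with -0.19 ± 0.0933 and -0.18 ± 0.0879. Their edgeR adjusted p lay between 0.291 and 0.431. Rbp4 and Ttr were highest in RetSat ko 5 (7.66 and 14.8 CPM), the library that also held the most Alb, a liver transcript chosen after its values were seen (94.7 CPM), and without it their log2 fold changes were 0.26 and 0.24. Adh1 passed the threshold without RetSat ko 1 (edgeR adjusted p = 0.0470).

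Markers of crypt cells stood toward higher values and markers of mature enterocytes toward lower values. All 22 tested cell cycle genes were positive (median 0.29), with 0.38 for Birc5, 0.31 for Tyms, 0.31 for Rrm2 and 0.29 for Cdk1. None passed over all genes tested and 10 were higher when adjusted over the list alone. Of 18 intestinal stem cell and Wnt genes, 16 were positive (median 0.20), with 0.47 for Sox9, 0.46 for Myc, 0.25 for Rgmb and 0.18 for Prom1. In edgeR 3 of them (Sox9, Myc and Rgmb) were higher when adjusted over the list alone. DESeq2 called Sox9 over all genes (adjusted p = 0.0366). Of 15 Paneth cell genes, 14 were positive (median 0.83), with 0.84 for Defa17, 1.303 for Defa22, 0.81 for Defa30 and 0.76 for Habp2, and none passed over all genes or adjusted over the list alone. The alpha-defensins are near-identical copies that share reads, so their single values are uncertain. Of 20 absorptive enterocyte genes, 18 were negative (median -0.35), with -0.58 for the disaccharidase Sis, -0.51 for the amino acid transporter Slc6a19, -0.53 for the lactase gene Lct and -0.34 for Treh, and none passed over all genes or adjusted over the list alone. Camera with the preset correlation called these lists with adjusted p of 8.47e-09, 0.000225, 7.70e-07 and 3.75e-06, and each had an adjusted p of 0.533 with an estimated correlation. When RetSat ko 1 was left out, 16 cell cycle genes and 3 stem cell genes (Sox9, Myc and Rgmb) were higher and 3 enterocyte genes (Sis, Slc6a19 and Treh) lower over all genes tested. In that fit 371 of all 19001 tested genes were higher and 475 lower. The voom median of the Paneth cell list was 0.55 without the 3 libraries highest in B cell transcripts, against 0.91 with all. The stem cell and Wnt call was lost without the 3 libraries highest in B cell transcripts (median 0.081, camera adjusted p = 0.0910). The genotype difference of the cell cycle score minus the enterocyte score was 0.62 ± 0.272 on the log2 scale (SE), and 0.055 ± 0.471 with the acinar, B cell and adipocyte scores as covariates.

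**Figure D2:**
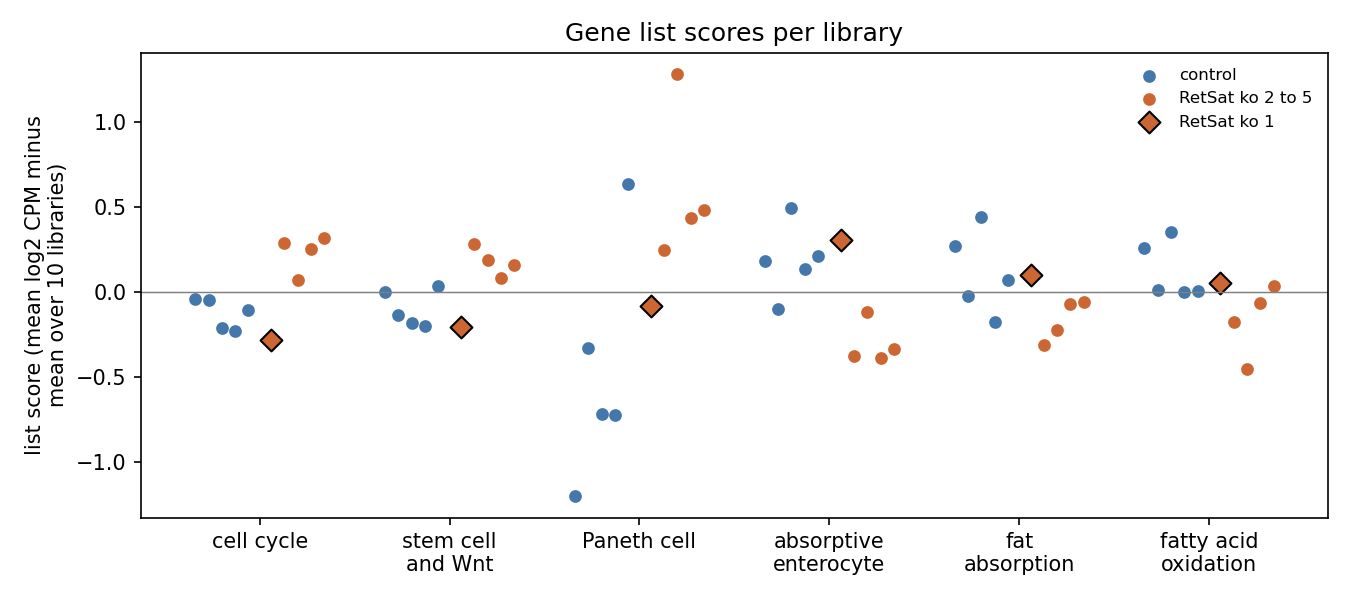
Score of 6 gene lists in each library, as the mean log2 CPM of the list's tested genes minus its mean over the 10 libraries, with control libraries in blue, RetSat ko 2 to 5 in orange and RetSat ko 1 as an orange diamond. For the cell cycle list RetSat ko 2 to 5 had scores of 0.071 to 0.32, RetSat ko 1 had -0.28 and the control libraries had -0.23 to -0.044.

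Of 24 genes of xenobiotic metabolism, 21 were negative (median -0.27), with -0.52 for the exporter Abcc2, -0.62 for Abcb1a, -0.31 for Ugt2b34 and -0.35 for the xenobiotic receptor Nr1i2. Of 14 tuft cell genes, 13 were negative (median -0.12), with -0.81 for Chat, -0.24 for Rgs13, -0.30 for Hpgds and -0.15 for Avil. Of 18 tight and adherens junction genes, 14 were negative (median -0.12), with -0.31 for Tjp1 and -0.25 for Ocln, whereas Cldn1 had 0.57. None of these members passed over all genes or adjusted over the list alone. Of 18 circadian clock genes, 16 were negative (median -0.26), with -0.71 for Cry2, -1.36 for Ciart, -0.57 for Nr1d2 and -0.31 for Npas2. Ciart was at 1.78 CPM in control 5, against 0.277 to 0.777 CPM in the other control libraries. In edgeR none passed over all genes, and 1 (Cry2) was lower when adjusted over the list alone. DESeq2 called Cry2 over all genes (adjusted p = 0.0190). Camera with the preset correlation called these 4 lists with adjusted p of 9.53e-06, 0.0126, 0.0168 and 0.00125. With an estimated correlation their adjusted p were 0.533, 0.533, 0.634 and 0.533. Cry2 passed over all genes without control 2 (edgeR adjusted p = 0.0368), and the junction list was not called without RetSat ko 2 (median -0.082, camera adjusted p = 0.126) or without the 3 libraries highest in B cell transcripts (median -0.039, adjusted p = 0.715). Voom medians moved from -0.28 to -0.18 for the xenobiotic list without control 3, and from -0.25 to -0.48 for the clock list without control 2. Without the B cell-rich libraries the voom median of the clock list was -0.16, and without the acinar-rich libraries that of the tuft cell list was -0.27, against -0.14 with all. With RetSat ko 1 left out, 3 xenobiotic genes (Ces2c, Cyp3a13 and Sult1b1) and 2 junction genes (Ocln and F11r) were lower over all genes. In that fit 475 of all 19001 tested genes were lower. Ces2c, Cyp3a13, Sult1b1 and F11r were chosen after their values were seen.

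Several immune and blood lists were also called with the preset correlation. All 25 interferon response genes were negative (median -0.44), with -0.44 for the RNA sensor Ddx58, -0.66 for Cxcl10 and -0.90 for Usp18. In edgeR none passed over all genes and 1 (Ddx58) was lower when adjusted over the list alone. DESeq2 called Ddx58 over all genes (adjusted p = 0.0366). All 14 genes of T cells and intraepithelial lymphocytes were negative (median -0.50), with -0.58 for Itgae, -1.43 for Cd8b1, -0.45 for Cd160 and -0.39 for Trdc. Of 9 MHC class II genes, 8 were negative (median -0.49), with -0.99 for H2-DMb1, -0.62 for H2-DMa and -0.61 for each of H2-Ab1 and Cd74. All 5 erythroid genes were negative (median -0.67), with -1.03 for Hba-a1, -0.67 for Hbb-bs, -0.70 for Hbb-bt and -0.61 for Alas2, and Hba-a1 was lower when adjusted over the list alone. All 10 plasma cell genes were positive (median 0.26), with 0.87 for Iglc1, 0.32 for Tnfrsf17, 0.93 for Ighm and 0.64 for Iglc2. Ighm was at 98.3 CPM in RetSat ko 2, against 11.6 to 33.5 CPM in the other RetSat ko libraries. Iglc2 was at 64.6 CPM in RetSat ko 4, against 13.1 to 41.1 CPM in the others. In edgeR no member of the T cell, MHC class II or plasma cell lists passed over all genes or adjusted over the list alone, and no erythroid gene passed over all genes. DESeq2 called Hba-a1 over all genes (adjusted p = 0.0254). The haemoglobin and immunoglobulin genes belong to families of similar copies, which makes their single values uncertain. The camera adjusted p were 1.23e-05, 8.54e-05, 0.00527, 0.00357 and 0.0268, and with an estimated correlation the adjusted p were 0.634, 0.634, 0.634, 0.533 and 0.634. Control 2 had the highest T cell and interferon scores (1.12 and 0.93). Without it the voom medians of these lists were -0.23 and -0.25, against -0.44 and -0.42 with all libraries (camera adjusted p = 0.0178 and 0.0130). The MHC class II call was lost without control 4 (voom median -0.17 against -0.42 with all, adjusted p = 0.0587), without RetSat ko 1 (0.0558) and without the 4 libraries highest in acinar transcripts (median -0.13, adjusted p = 0.224). Control 4 had the highest MHC class II score (1.09, with 1295 CPM of Cd74 against 353 to 673 CPM in the other libraries) and the highest B cell score among the control libraries (2.50). The erythroid call was lost without the 3 libraries highest in B cell transcripts (median -0.24, adjusted p = 0.193) and without the 4 libraries highest in acinar transcripts (-0.48, adjusted p = 0.0991). The plasma cell call was lost without control 1 (0.189), control 2 (0.153), control 3 (0.0631), RetSat ko 3 (0.0790) or RetSat ko 4 (0.0561), with 1 surrogate variable (0.0841) and with the acinar score as a covariate (0.109). Its voom median was 0.18 without control 1, 0.21 without RetSat ko 3, 0.52 without control 4 and 0.99 without the acinar-rich libraries, against 0.33 with all. Ddx58 passed over all genes without RetSat ko 1 (edgeR adjusted p = 0.0263).

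In all, camera with the preset correlation called 17 of 36 lists, 6 toward higher and 11 toward lower values. With an estimated correlation, and in fry, which tests whether the members move on balance in 1 direction, 0 lists passed (lowest adjusted p = 0.533 with an estimated correlation, and 0.263 in fry). At an unadjusted p under 0.05 these tests put 0 and 3 lists past the threshold. Of 100 splits of the 10 libraries into 5 and 5, 26 put at least 17 lists past the threshold with the preset correlation. Of the 569 tested members, 0 passed over all genes in edgeR, where 100 had an unadjusted p under 0.05. Among all 18654 tested genes, 2283 had an unadjusted p under 0.05. DESeq2 called 10 of the 569 members and limma-voom 0, and 10 lists held a member that passed when adjusted over the list alone.

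Transcripts of other tissues varied between libraries within each genotype. The pancreatic acinar genes Clps and Cela1 had 25.9 and 14.3 CPM in control and 65.3 and 78.8 CPM in RetSat ko, the B cell genes Cxcr5 and Bank1 0.621 and 1.95 against 2.41 and 3.60 CPM, and the adipocyte genes Retn and Lipe 0.0361 and 138.9 against 0.529 and 118.0 CPM. None of these genes passed in edgeR (adjusted p from 0.323 to 0.625). RetSat ko 2 alone held 168.3 CPM of Clps and 314 CPM of Cela1, against 27.4 to 52.0 and 7.34 to 55.5 CPM in the other RetSat ko libraries. The acinar score was highest in RetSat ko 2 and ko 1 and control 5 and 4 (6.83, 4.37, 3.52 and 2.49 on the log2 scale), and below 0 in the other 6. The B cell score was highest in RetSat ko 2, control 4 and RetSat ko 3 (3.84, 2.50 and 1.96), and below 0 in the other 7. The adipocyte score was highest in RetSat ko 5, ko 4 and ko 3 and in control 3 (2.48, 2.01, 1.69 and 1.19). In every library 2 of 13 acinar, 4 of 9 B cell and 3 of 10 adipocyte genes had at least 1 CPM, so these lists are not free of background from the jejunum. None of these 3 scores was found to differ between the genotypes (two-sided exact permutation tests, adjusted p = 0.702, 0.492 and 0.400). These lists had camera adjusted p of 0.0884, 0.0613 and 0.0707 (adjusted p = 0.801, 0.713 and 0.713 with an estimated correlation), and their calls depended on the setting. The acinar list passed without control 4 (0.0490), control 5 (0.0249), RetSat ko 3 (0.0142) or RetSat ko 5 (0.00529), the B cell list without control 4 (0.00283), RetSat ko 4 (0.00931) or RetSat ko 5 (0.00192), and the adipocyte list without control 3 (0.0136), RetSat ko 1 (0.0137) or RetSat ko 2 (0.0125). The B cell and adipocyte lists also passed with RLE factors (0.0440 and 0.0478), without a filter (0.0187 and 0.0255) and with sample weights in limma-voom (0.0391 and 0.0124), and the adipocyte list with 1 surrogate variable (1.88e-06) and with the acinar score as a covariate (1.73e-06). Without the 4 acinar-rich libraries all 3 lists passed (0.0308, 0.0121 and 0.000166), and without the 3 B cell-rich libraries the acinar and B cell lists did (0.0158 and 0.00344). The voom median of the B cell list was 1.02 and 0.38 in these fits, against 1.58 with all libraries. That of the acinar list ranged from -0.60 to 3.45 over the 21 settings with the preset correlation. In fits added after seeing the data, edgeR called 5 genes without the 4 libraries highest in acinar transcripts, 4 genes without the 3 highest in B cell transcripts, and 6 genes with the acinar score as a covariate.

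The other lists were not called. The antimicrobial and acute phase list had a camera adjusted p of 0.301, with log2 fold changes of 1.48 ± 0.465 for Reg3g and 1.80 ± 0.641 for Reg3b, related lectins against bacteria, and it passed without control 4 (0.0463), without the 4 acinar-rich libraries (0.0173) and without the 3 B cell-rich libraries (0.0115). In the p53 and apoptosis list (0.793), Phlda3 had 0.65 ± 0.155 and was higher when adjusted over the list alone, and over all genes without RetSat ko 1 (edgeR adjusted p = 0.0274). DESeq2 called Phlda3 over all genes (adjusted p = 0.0168). In the list of blood and lymphatic endothelium (0.942), Vwf had -0.40 ± 0.109 and was lower when adjusted over the list alone. DESeq2 called Vwf over all genes (adjusted p = 0.0366). The endothelium list had a positive median (0.059) with a test in the lower direction. It was called in the higher direction without RetSat ko 1 (camera adjusted p = 0.0432) and without the 4 acinar-rich libraries (0.00251). Without RetSat ko 1 its adjusted p was 0.521 with an estimated correlation and 0.0849 in fry. The enteroendocrine list (0.0707) passed without control 3 (0.0310), control 5 (0.0316), RetSat ko 4 (0.0415) or RetSat ko 5 (0.00789). The smooth muscle list (0.0884) passed without control 1 (0.0160), control 2 (0.0367), control 4 (0.0204) or RetSat ko 5 (0.0134), and the list of enteric neurons and glia (0.0707) without control 1 (0.0104), control 2 (0.0422) or RetSat ko 5 (0.0199). These 3 lists also passed without a filter (0.0397, 0.0486 and 0.0395). The fibroblast list (0.873) passed in the higher direction without the 4 acinar-rich libraries (median 0.29, camera adjusted p = 0.00923). With all libraries the antimicrobial, enteroendocrine, smooth muscle, neuron and glia, endothelium and fibroblast lists had adjusted p = 0.713, 0.634, 0.801, 0.713, 0.991 and 0.991 with an estimated correlation. The goblet cell (0.964), mast cell (0.976), macrophage and dendritic cell (0.728), antioxidant (0.728), unfolded protein response (0.536), immediate early (0.986), proximal intestine (0.397) and distal intestine (0.976) lists did not pass. The medians of the goblet cell, antimicrobial and mast cell lists also differed in sign from their tests.

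Over the 500 most variable genes, the first principal component held 35.95% of the variance and the second 15.3%. Mean scores on the first component were -4.31 ± 23.0 in control and 4.31 ± 25.1 in RetSat ko (SD, n = 5 each), with no difference found (two-sided exact permutation p = 0.579). On the second they were -9.11 ± 7.46 and 9.11 ± 15.8 (exact permutation p = 0.0635, adjusted p = 0.127). RetSat ko 2 to 5 had second component scores of 11.2 to 23.8, RetSat ko 1 had -17.8 and the control libraries had -16.1 to 2.28. After leaving out RetSat ko 1 the second component separated the genotypes (adjusted exact permutation p = 0.0159). This removes the only RetSat ko library whose score did not lie above all control libraries, so the choice of library favours the separation.

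Several called genes lie on chromosome 6, which carries Retsat. With Retsat left out, 4 of the 5 remaining called genes (BC064078, Gm45063, Gm5154 and Gm45053) lie on chromosome 6, which holds 1086 of 18653 tested genes (1-sided Fisher's exact test, adjusted p = 0.00120). Gm45053 overlaps Retsat, and it is the only called gene within 10 Mb of Retsat, where 176 tested genes lie (Fisher's exact p = 0.0463). Because its reads cannot be told apart from those of the deleted gene, this p does not bear on clustering near Retsat. With Gm45053 left out too, a test added after seeing the data, 3 of 4 called genes lie on chromosome 6 (Fisher's exact adjusted p = 0.0165) and 0 within 10 Mb of Retsat. The other 3 start between 128969915 and 132439465. Fisher's exact test treats called genes as independent, which neighbouring genes may not be, so the adjusted p of 0.00120 and 0.0165 may be too small. Among the 845 genes called without RetSat ko 1, 47 lie on chromosome 6, which is no enrichment (Fisher's exact adjusted p = 1). Chromosome 17, with 63 of its 966 tested genes called, was the only chromosome that passed there (Fisher's exact adjusted p = 0.0328). The call within 10 Mb of Retsat was lost without control 2, control 5, RetSat ko 4 or RetSat ko 1 (Fisher's exact p = 0.0552, 0.0556, 0.0729 and 0.988).

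**Figure D3:**
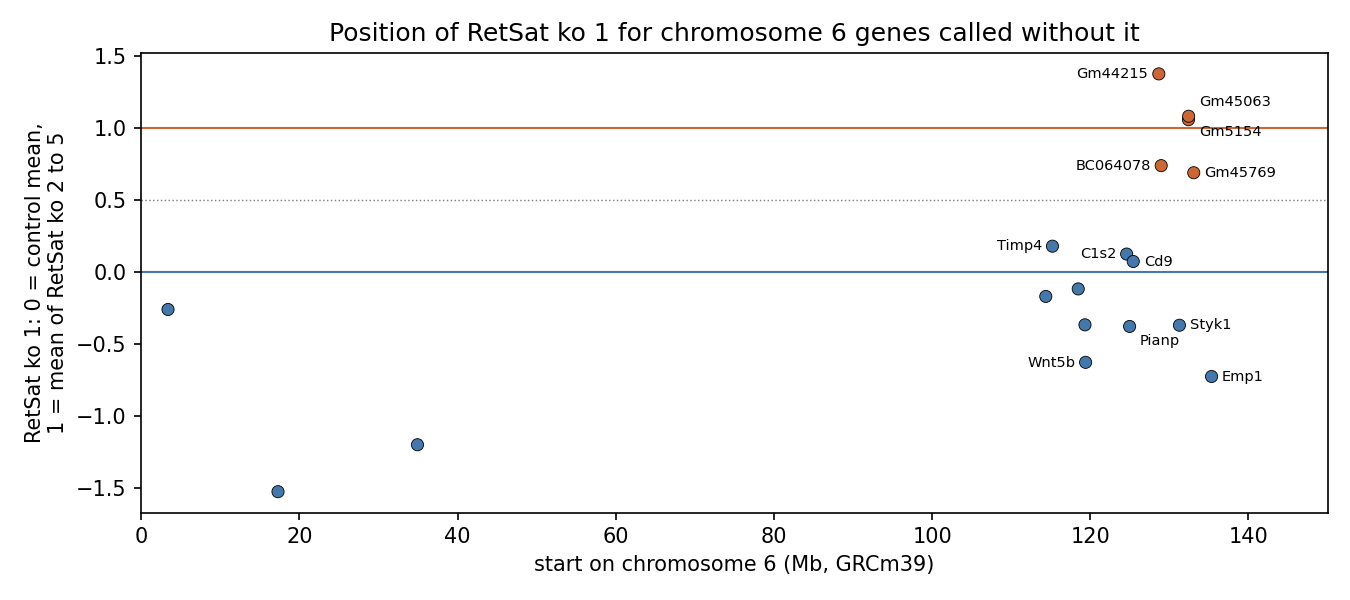
Position of RetSat ko 1 between the control mean (0, blue line) and the mean of RetSat ko 2 to 5 (1, orange line) in log2 CPM, for the 18 chromosome 6 genes that were called without RetSat ko 1 with an absolute log2 fold change of at least 0.5, against their start in Mb on GRCm39. Each point is 1 gene, orange where RetSat ko 1 lay nearer RetSat ko 2 to 5. These 5 genes start between 128668036 and 133087437, and the other 13 are blue. Retsat and Gm45053, which start at 72575458 and 72579987, met the same conditions but were left out. In both, RetSat ko 1 lay nearer RetSat ko 2 to 5.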

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

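The test of a mislabelled library, the choice of RetSat ko 1 among the libraries left out, and the demand below on the error of the tissue test were chosen only after the results were seen. A value is listed here when the highest or lowest library of its genotype lay apart from the other 4 by a gap large against the range of the group (Dixon's criterion). Of 332 groups of 5 that were looked at, 52 were listed, where chance lists about 1 in 20 (16.6), and genes that vary together are not independent.

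RetSat ko 1 stood apart from RetSat ko 2 to 5 in 20 values. Its TMM factor was 0.889 against 1.06 to 1.08, and its 10 most abundant genes took 9.71% of the counts against 7.70 to 8.18%. It was the highest for Apob (4246 CPM against 2624 to 2874), Treh (958.9 against 650.6 to 710.9), Nr1i2 (167.9 against 116.8 to 124.7), Rxra (236.1 against 174.4 to 189.5), Gapdh (1986 against 987 to 1186), Styk1 (110.2 against 57.5 to 67.6), Emp1 (493 against 238 to 297), Ehhadh (397.9 against 208.8 to 252.1), Tm6sf2 (503.9 against 364 to 385.6), F11r (356.1 against 221.3 to 254.5), Sult1b1 (637.5 against 386.8 to 444.6) and Sc5d (241 against 138.4 to 148.6). It was the lowest for Gm13394 (0.304 against 72.5 to 87.0), C1s2 (0.0392 against 0.326 to 0.412), Pianp (1.18 against 3.38 to 4.12) and Wnt5b (0.921 against 3.09 to 3.71). Its fibroblast score was -0.57 against 0.11 to 0.31 in the others, and its score for blood and lymphatic endothelium -0.64 against 0.072 to 0.25. Gapdh, Gm13394, C1s2, Pianp, Wnt5b, Styk1, Emp1, Ehhadh, Tm6sf2, F11r, Sult1b1 and Sc5d were chosen after their values were seen. Most of these 12 were picked from genes called without this library, which favours its standing apart in them.

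The other listed values are given without explanation. RetSat ko 5 was the highest for Retsat (33.4 CPM against 15.4 to 16.8 in the other RetSat ko libraries), Rbp4 (7.66 against 2.84 to 3.46), Ttr (14.8 against 5.62 to 7.63) and 3 genes chosen after their values were seen, Alb (94.7 against 1.14 to 3.01), Ahsg (7.27 against 0.0172 to 0.165) and Gc (7.65 against 0.0172 to 0.210). It was the lowest for March7 (44.0 against 53.1 to 56.2). RetSat ko 2 was the highest for Clps (168.3 against 27.4 to 52.0), Cela1 (314 against 7.34 to 55.5), Ctrb1 (512 against 0.189 to 106.8), Cxcr5 (9.35 against 0.172 to 1.96), Bank1 (10.4 against 1.10 to 2.96), Ms4a1 (21.6 against 0.310 to 4.49) and Ighm (98.3 against 11.6 to 33.5). Ctrb1 and Ms4a1 were chosen after their values were seen. RetSat ko 3 was the highest for Habp2 (6.65 against 2.66 to 3.43). Control 4 was the highest control library for Cxcr5 (2.54 against 0.0643 to 0.207), Bank1 (4.40 against 1.10 to 1.60), Ms4a1 (6.84 against 0.115 to 0.213), Ighm (47.2 against 8.10 to 15.5), the B cell score (2.50 against -1.95 to -1.13), Adh4 (153 against 93.4 to 105), Ehhadh (444.7 against 313.6 to 330.9) and BC064078 (1.7 against 0.804 to 1.05). Control 2 was the highest for Mvd (25.0 against 17.2 to 19.4) and Cd160 (5.12 against 2.29 to 2.99) and the lowest for Myc (9.88 against 13.4 to 14.8) and Sis (5231 against 6193 to 6362). Control 3 was the highest for Retn (0.150 against 0 to 0.0307) and Timp4 (0.224 against 0.0464 to 0.0768), and the lowest for Vwf (8.48 against 9.27 to 9.38) and the smooth muscle score (-1.25 against -0.084 to 0.27). Control 5 was the highest for Ttr (6.62 against 5.02 to 5.34).

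The first pattern is the contrast between crypt and enterocyte markers. The cell cycle score minus the enterocyte score was 0.19 to 0.66 in RetSat ko 2 to 5, -0.59 in RetSat ko 1 and -0.71 to 0.051 in control, a genotype difference of 0.62 ± 0.272 on the log2 scale (SE, two-sided exact permutation p = 0.0635). A wrong label on RetSat ko 1 is argued against by its 16.8 CPM of Retsat, where the lowest control library had 340. With the proximal score as covariate the difference was 0.60 ± 0.258, as predicted if place along the intestine was not the cause. That score differed by only -0.11 between the genotypes (two-sided exact permutation p = 0.865), so the covariate could hardly move the difference. It was 1.215 in RetSat ko 1, -0.86 to 0.18 in RetSat ko 2 to 5 and -0.85 to 1.01 in control. Place is therefore not argued against. With the acinar, B cell and adipocyte scores as covariates the difference was 0.055 ± 0.471, a fall that had been predicted if other tissue in the samples (up to 512 CPM of Ctrb1, 21.6 of Ms4a1 and 6.58 of Adipoq, also chosen after its values were seen) was the cause, and the prediction as written was met. A demand that the error be small enough was added after the value was seen, and under it other tissue and an effect of the genotype cannot be told apart, because the value plus its SE lay above the bound set in the prediction.

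Against other splits of the 10 libraries into 5 and 5, the genotype split gave 6 genes and the highest of the others gave 1, so 1 of 100 splits reached the count. This partly restates the design, since the 6 include Retsat, Gm45053 (reads not told apart from those of Retsat) and Esr1 (hormone-binding domain carried by the transgene in modified form). The other 3 still outnumbered the highest other split. They lie close together on distal chromosome 6 and may not be independent, so chance is not excluded on their count alone. For the lists, 26 of 100 splits gave as many as the 17 of the genotype split, and the highest other split gave 22, so chance cannot be excluded. Without RetSat ko 1 the genotype split gave 846 genes and the highest of the others gave 54, so 1 of 100 splits reached the count. That library is the 1 of 10 whose removal gives the most calls, and the other splits were not given such a choice.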

How the results depend on the processing

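The fits without the libraries richest in acinar or B cell transcripts, and the tests of lists without RetSat ko 1 in fry and with an estimated correlation, were chosen only after the data were seen. Retsat kept its direction in all 24 fits and its call in 23. Without the 4 libraries highest in acinar transcripts, which leaves 3 against 3, its log2 fold change was -4.51 with an edgeR adjusted p of 0.0918. Esr1 and BC064078 were called in all 24 fits. The count of called genes was 6 with RLE factors, upper-quartile factors, limma-voom and a surrogate variable, the same 6 genes in each. It was 9 without a filter, 4 with a filter of 1 CPM, 10 with sample weights in limma-voom and 123 in DESeq2. The DESeq2 count included 3 of the 6, and DESeq2 gave no adjusted p for the other 3 nor for 6881 genes in all. The cause of the higher counts was not tested. Leaving out 1 library gave 5 to 846 genes, the highest without RetSat ko 1 and 5 to 9 otherwise. Replicate numbers did not pair the libraries (correlations of deviations from -0.149 to 0.002, and 0 of 5 control libraries matching their own number best). With the replicate block 4 genes were called, 3 of them shared, and Gm45063, Gm45053 and Gm5154 were lost (edgeR adjusted p = 0.270, 0.223 and 0.447). Their log2 fold changes there were 9.287, -1.356 and 7.635, against 9.297, -1.354 and 7.655 in the main fit. Under the block the chromosome 6 enrichment had an adjusted p of 1, as did Fisher's exact test near Retsat (exact p = 1). The acinar, B cell, adipocyte and enteroendocrine lists passed under it (camera adjusted p = 0.0108, 0.0150, 0.0150 and 0.0447). The lists past the threshold numbered 16 to 21 without single libraries, but 0 with an estimated correlation and 0 in fry. Without RetSat ko 1, fry called 2 lists, cell cycle (adjusted p = 0.0225) and stem cell and Wnt (0.0314), while the lowest adjusted p with an estimated correlation was 0.360. The endothelium list turned the direction of its test without RetSat ko 1 (median 0.19, from -0.028 to 0.19 without single libraries) and without the 4 acinar-rich libraries (0.25), and the cholesterol list, with a median of 0.015, in the latter. The distance on the second component ranged from 11.4 to 27.96 without single libraries, past the threshold without RetSat ko 1. The chromosome 6 enrichment had adjusted p of 8.54e-05 to 1 without single libraries, lost without RetSat ko 1, whose removal adds calls elsewhere. The region within 10 Mb of Retsat had p of 0.0372 to 0.988 without single libraries 0.0642 for genes called at 0.1 and 1 with Gm45053 left out, a choice made after the data were seen. Among the other values, 2833 of 2908 for named genes kept direction and side of the threshold, 10 lost it, 65 gained it and 0 turned, and for the lists 684 of 791 kept them, 59 lost it, 45 gained it and 3 turned. Depth limits single-gene statements for genes with few counts, such as Gm5154, with 17 to 41 counts in RetSat ko libraries.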

Other observations

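The tests of transgene reads, of the gene order on chromosome 6 and of counting noise, and the ribosomal protein list, were chosen only after the results were seen. Ribosomal protein genes, a list added after seeing the data, stood toward higher values in RetSat ko. Of 85 tested genes, 83 were positive with a median log2 fold change of 0.22, and 0 passed over all genes in edgeR. The camera p was 1.28e-38 with the preset correlation and p = 0.0452 with an estimated correlation. Without RetSat ko 1, 34 of them were higher over all genes in edgeR, with a camera p of 0.0610 with an estimated correlation. These camera p are not adjusted, unlike those of the 36 lists. Because the list was chosen after the data were seen, they cannot serve as a test of it. Many ribosomal protein genes have processed copies in the genome, so reads shared with those make single values uncertain.

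Esr1 was higher in every RetSat ko library, by a log2 fold change of 6.00. A larger share of stromal cells, which are known to express Esr1, is argued against by the fibroblast list, whose median log2 fold change was 0.058 and whose highest member was 0.44. The lowest RetSat ko library had 48.5 times the Esr1 level of the highest control library. A candidate explanation is that reads of the Cre-ERT2 transgene, which contains a hormone-binding domain of the oestrogen receptor, were counted for Esr1. Because the transgene is present in each RetSat ko sample and absent from each control sample, this hypothesis and a response of the gene itself cannot be told apart from gene counts.

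A further pattern concerns distal chromosome 6. BC064078, Gm45063 and Gm5154 were higher in all 5 RetSat ko libraries, with the 95% Poisson interval of the lowest RetSat ko library at least 6.21 counts above that of the highest control library, which does not test counting noise, since these genes were picked for being higher. A candidate explanation is a segment of another origin shared by the Cre-positive mice, of which RetSat ko 1 carries a shorter part. Retsat and Gm45053, which start at 72575458 and 72579987, were also called without RetSat ko 1 but were left out of the gene order. In both, RetSat ko 1 (16.8 and 0.696 CPM) lay with the other RetSat ko libraries, and the order with them was not tested. The following counts cover 18 other chromosome 6 genes called without RetSat ko 1 and changed by at least 0.5 on the log2 scale. RetSat ko 1 lay with the other RetSat ko libraries in 5 of them (Gm44215, BC064078, Gm5154, Gm45063 and Gm45769). It lay nearer control in 13 (including Timp4, Wnt5b, C1s2, Pianp and Cd9, chosen after their values were seen). Over all genes called without RetSat ko 1, this library lay nearer control in 88.95%, so a nearer position is not particular to chromosome 6. Styk1 and Emp1 were the 2 genes out of order for a single change point (permutation p = 0.0345 over 100000 gene orders). The hypothesis was formed on these data, the genes were selected by leaving out that library, and descent and an effect of the loss of Retsat were not separated by a test.

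Gm13394, a processed pseudogene on chromosome 2 (28823622 to 28824621) chosen after its values were seen, had 72.5 to 87.0 CPM in RetSat ko 2 to 5, 0.304 CPM in RetSat ko 1 and 0.176 to 0.377 CPM in control. Its edgeR log2 fold change was 7.94 ± 1.299 with an adjusted p of 0.216. Its transcript is 99.9% identical over 1000 bases to that of Gapdh, which lies at 125138678 to 125143430 on chromosome 6, and 35 genes other than Gm13394 match it at 98% or more, so its reads are uncertain. Whether they were shared reads was also tested after the values were seen, and the match met what had been set for it. A match of sequence cannot show that reads were shared, so the test decides nothing and is not weighed further. Gapdh had 1359 to 1598 CPM in control, 987 to 1186 CPM in RetSat ko 2 to 5 and 1986 CPM in RetSat ko 1.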
